A study of Homo sapiens with 14 samples.

How the data were processed

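Bulk RNA was sequenced from tumours of 7 patients, 4 with colorectal cancer (CRC) and 3 with melanoma. Each patient gave 1 intact tumour library and 1 library of dissociated tumour cells, so the 14 libraries form 7 pairs. Per the labels' protocol, both preparations were viably frozen and thawed, RNA was taken with a column kit for small samples, and libraries were made with an exome-capture RNA kit, which enriches fragments of coding exons with probes. Patients are named here by tumour type and replicate number, given in the order of the records.

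The authors deposited TPM, a transcript abundance scaled to one total, per gene for each tumour type, and the submitters' processing notes name Salmon 1.10.1 and the GRCh38 p14 build. The annotation, the step from transcripts to genes and any filter are not given in the sources used here. Each TPM column sums to 1000000 over 56809 gene symbols. TPM keeps no read depth, so the depth of each library is unknown and no counting interval can be given. All 56809 symbols are gene names of GENCODE release 29, from which gene identifiers, gene types and GRCh38 coordinates were taken; 219 symbols name more than 1 identifier.

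The authors also deposited a score per gene for each tumour type, which the table's name ties to log2 TPM, a TCGA reference and unit variance. Among genes that varied, 100% of the scores followed a straight line of log2(TPM + 1) within each preparation, at a correlation above 0.99, and the mean lay near 0 in each preparation. A difference between preparations is therefore removed from these scores by their construction. They were used as an alternative only. The score tables hold 936 CRC rows and 593 melanoma rows without a gene name, which were left out.

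Values were tested as log2(TPM + 1), so fold changes are on that scale and understate the change of low genes. Genes with a TPM of at least 1 in at least 3 libraries of a fit were kept. limma 3.58.1 in R 4.3.3 was used (eBayes with a trend, two-sided, Benjamini-Hochberg adjustment over all genes tested, threshold 0.05). The preparation comparisons used all 14 libraries with the patient as a block, with 1 preparation effect, with 1 effect per tumour type, or with the difference between those effects. Melanoma was compared with CRC among the 7 intact and among the 7 dissociated libraries. The pairing comes from the patient codes and the protocol in the labels. As a check, deviations from the group means correlated within every pair, at 0.417 to 0.798. No 2 libraries were duplicates, since the highest correlation between any 2 was 0.952. In a check for mixed-up samples, given only as a count, the libraries of 1 patient did not match each other under simple thresholds, which may be too strict. All patients were kept, and each was left out in turn as an alternative.

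A total of 33 gene lists for stress responses, cell types and housekeeping functions was fixed, and each had at least 5 tested genes. A list's value is the mean log2(TPM + 1) of its tested genes, dissociated minus intact per pair. It was tested with an exact two-sided sign-flip permutation of the 7 pairs (128 flips), with Benjamini-Hochberg adjustment over the 33 lists. Beside it stand limma's camera with a preset inter-gene correlation of 0.01 and with an estimated one, and counts of members adjusted over the list alone. Library measures used the same exact test, and the shares of snoRNA, protein-coding, immunoglobulin and SNORD3A genes among them were chosen after seeing the TPM tables. The correlation of each intact library with the dissociated library of its own patient was tested with all 144 assignments of patients within tumour type.

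The genes named were chosen by rule. For the preparation comparison over all patients and for tumour type in intact tissue, these are the 10 largest changes in each direction past the threshold. They must have the same direction in every pair, or no overlap between groups, and a mean TPM of at least 5 in the higher group. The other comparisons use the 5 largest. Where no gene passed in a direction, the 3 with the smallest p are given. Up to 4 members with the smallest p represent a list. XIST, genes on chromosome Y and the V, D and J segments of antigen receptors were left out, and not every gene that the rule selects is named. The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined.

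The alternatives fixed beforehand were a pseudocount of 0.1, no filter, quantile normalization, TPM rescaled without mitochondrial, ribosomal protein, haemoglobin and immunoglobulin genes, eBayes without a trend, no patient block, each tumour type fitted alone, the authors' scores, and leaving out each patient. Scaling protein-coding genes to one total, a robust prior, protein-coding genes only and further checks without 1 patient were added after seeing the data. The limma step was tested on simulated data with 200 changed genes of 16080 tested. In the all-patients comparison it recovered 25.4% of genes changed by 1 on the log2 scale, 77.6% of those changed by 2 and 93.9% of those changed by 4. It also called 10 unchanged genes. The simulated genes varied independently and the unchanged ones had no shift, unlike the real data, so recovery there may differ. Plots were drawn with matplotlib 3.10.9. The patients' own variation sets the error, and the tumours were sampled in different organs, which cannot be separated from tumour type.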

Results

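Gene expression was measured in intact tumour tissue and in dissociated tumour cells of the same 7 patients, 4 with CRC and 3 with melanoma as TPM. The design allows intact tissue and dissociated cells to be compared within patients, and tumour types to be compared within each preparation. An effect of dissociation itself cannot be parted from other differences between the samples of a patient. Each library had 11007 to 14863 genes with a TPM of at least 1. Depth is unknown, since TPM does not keep it.

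Small nucleolar RNAs (snoRNAs), many of which guide the modification of ribosomal RNA, held a large part of TPM, and their share was lower in dissociated cells. TPM divides reads by transcript length, so short genes weigh more and a share of TPM is not a share of reads. The snoRNA share of TPM was 49.6% ± 5.83 (SD, n = 7) in intact tissue and 35.5% ± 8.99 (SD, n = 7) in dissociated cells, lower in 7 of 7 pairs. The protein-coding share was 35.6% ± 4.60 (SD, n = 7) in intact tissue and 46.1% ± 8.20 (SD, n = 7) in dissociated cells, higher in 7 of 7 pairs. Immunoglobulin genes held 2.28% ± 5.13 (SD, n = 7) in intact tissue and 3.39% ± 5.53 (SD, n = 7) in dissociated cells, higher in 7 of 7 pairs. Both means rest largely on CRC patient 3, at 13.9% and 15.6%. The number of genes with a TPM of at least 1 rose from 12338 to 13407 on average, and the share of the 100 highest genes fell from 69.2% to 60.7%, again in 7 of 7 pairs. A single snoRNA gene, SNORD3A, held 26.9% of TPM in intact tissue and 20.9% in dissociated cells, higher in 3 of 7 pairs and lower in 4 (exact p = 0.203). The snoRNA, protein-coding, immunoglobulin, gene number and 100-gene measures, 5 in all, each had an exact sign-flip p of 0.0156, the smallest that 7 pairs can give, and an adjusted p of 0.0281 over 9 measures. The shares of mitochondrially encoded genes (exact p = 0.656) and of ribosomal protein genes (exact p = 0.109) did not pass. Because the shares must sum to one total, TPM of other genes shifted upward: the median log2 difference over all genes tested was 0.39 as deposited, 0.12 with protein-coding genes set to one total and -0.02 after quantile normalization. Values below are as deposited unless another scaling is named.

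**Figure D1:**
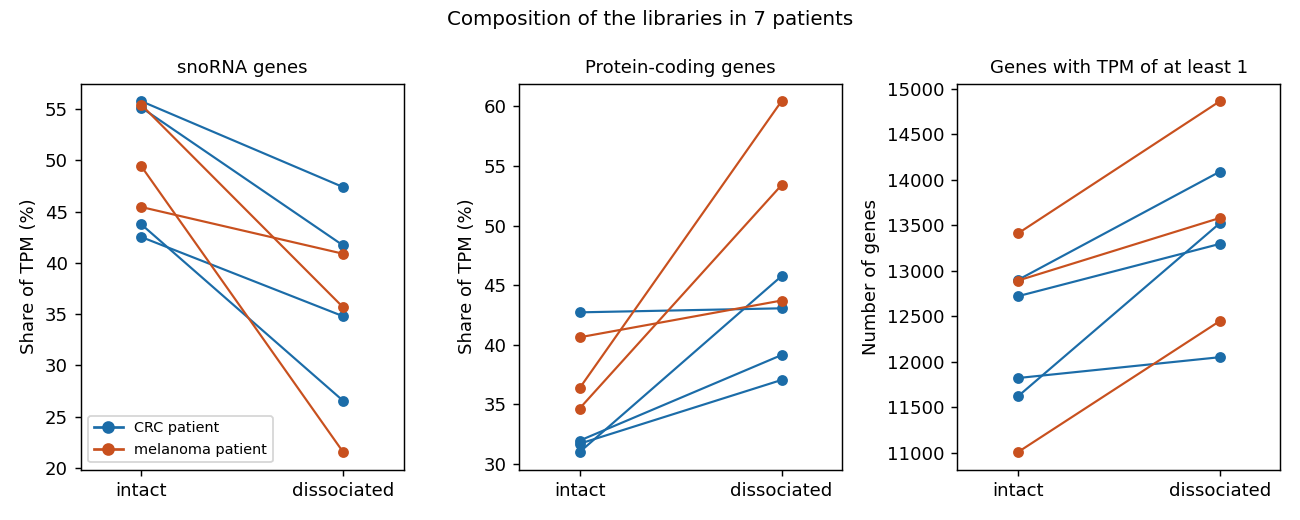
Share of TPM in snoRNA genes and in protein-coding genes (percent) and number of genes with a TPM of at least 1, in intact tissue and dissociated cells; each line joins the 2 libraries of 1 patient. The snoRNA share was lower and the other 2 measures were higher in dissociated cells in 7 of 7 pairs.

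Immediate-early genes, transcription factors and feedback regulators that respond within minutes to stimulation, were higher in dissociated cells. Adjusted over the list alone, 26 of the 33 tested members rose and none fell, and 26 rose with protein-coding scaling. The list's mean difference was 1.49 ± 0.82 on the log2 scale (SD, n = 7), higher in 7 of 7 pairs, and 1.19 with protein-coding scaling. NR4A2, a nuclear receptor on chromosome 2 (156324432 to 156342348), rose from a mean TPM of 15.5 ± 32.3 (SD, n = 7) to 62.8 ± 109 (SD, n = 7), with a log2 fold change of 2.32 ± 0.29 (SE). In CRC its mean TPM rose from 2.99 to 21.6, and in melanoma from 32.3 to 118. ZFP36, which speeds the decay of cytokine mRNAs and lies on chromosome 19 (39406813 to 39409412), rose by 2.07 ± 0.27 (SE). JUND, a subunit of the AP-1 transcription factor, rose by 2.01 ± 0.29 (SE), and KLF4 rose by 1.73 ± 0.25 (SE), each in 7 of 7 pairs. These genes passed limma's test only over the list alone, at adjusted p of 0.000279 to 0.000353, and none passed over all genes. The list had an exact sign-flip p of 0.0156, which became 0.0645 over the 33 lists. Its camera adjusted p was 1.87e-14 with the preset correlation, and adjusted p = 0.629 with an estimated correlation.

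T cell genes were higher as well. Adjusted over the list alone, 17 of 20 tested members rose, as against 13 with protein-coding scaling and 3 after quantile normalization. The mean difference of the list was 1.38 ± 1.16 (SD, n = 7), higher in 7 of 7 pairs, and 1.17 with protein-coding scaling. The count was 11 without CRC patient 4 and 7 without melanoma patient 2. TRBC2, a constant segment of the T cell receptor, rose by 2.10 ± 0.40 (SE) and CD3D, a subunit of its signalling complex, by 2.03 ± 0.41 (SE). IL7R, the receptor chain for interleukin-7, rose by 2.54 ± 0.55 (SE) from a mean TPM of 38.4 to 182, in 6 of 7 pairs, and TRAC rose by 1.73 ± 0.46 (SE). The largest difference of the list, 3.76, was in melanoma patient 1, where the melanocytic list differed by -1.73. The exact sign-flip p was 0.0156 (0.0645 adjusted), and the camera adjusted p = 0.774 with an estimated correlation. Of the cytotoxic and natural killer genes, 9 of 15 rose adjusted over the list alone, including PRF1 at 1.38 ± 0.39 (SE) and GZMB at 1.36 ± 0.41 (SE), which encode killing proteins of granules. With protein-coding scaling 0 of them passed, while the list's mean difference was 0.77, higher in 6 of 7 pairs (exact sign-flip p = 0.0469). That list differed by 0.97 ± 1.03 (SD, n = 7), higher in 6 of 7 pairs, with a camera adjusted p = 0.820 at an estimated correlation.

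**Figure D2:**
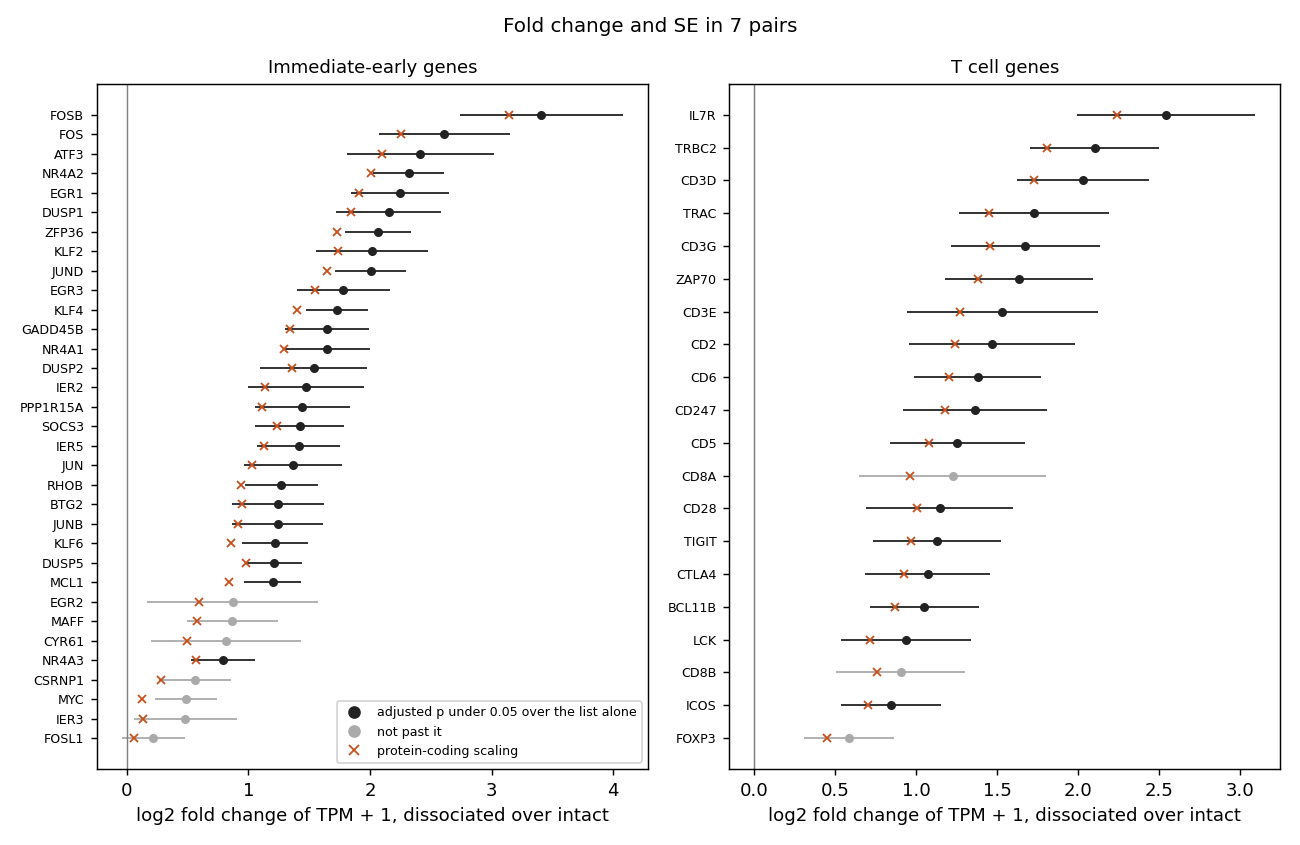
Log2 fold change of TPM + 1, dissociated over intact, for each tested immediate-early gene and T cell gene in 7 pairs; points are limma estimates with SE, black where the adjusted p over the list alone is under 0.05, and crosses are the estimates with protein-coding scaling. All points lie above 0, and 26 of 33 immediate-early and 17 of 20 T cell genes are black.

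Inflammatory, plasma cell and heat shock genes moved in the same direction in part of their members. Of 23 cytokine and NF-kB response genes, 7 rose adjusted over the list alone, and 3 with protein-coding scaling. The 7 became 13 without CRC patient 1 and 4 without CRC patient 2, CRC patient 4 or melanoma patient 2. CCL4 and CCL3, chemokines with closely related copies that share reads, rose by 2.78 ± 0.45 (SE) and 2.70 ± 0.57 (SE), and TNFAIP3, an inhibitor of NF-kB signalling, by 2.02 ± 0.37 (SE). The list differed by 0.93 ± 0.60 (SD, n = 7), higher in 7 of 7 pairs, and by 0.67 with protein-coding scaling, with a camera adjusted p = 0.774 at an estimated correlation. Of 12 plasma cell genes, 5 rose, among them the immunoglobulin constant genes IGHG1 by 1.75 ± 0.34 (SE) and IGKC by 2.12 ± 0.44 (SE), and 4 rose with protein-coding scaling. The list differed by 0.98 ± 0.75 (SD, n = 7), and by 0.72 with protein-coding scaling, with a camera adjusted p = 0.778 at an estimated correlation. Of 20 heat shock genes, 5 rose, led by HSPA1B at 2.83 ± 0.60 (SE) and HSPA1A at 2.13 ± 0.50 (SE), near-identical copies whose TPM may be split between them, and 3 rose with protein-coding scaling. Of 12 MHC class I genes, 4 rose, with HLA-B at 1.18 ± 0.25 (SE), and 1 rose with protein-coding scaling. The mean differences of heat shock genes, 0.73 ± 0.57 (SD, n = 7), and of MHC class I genes, 0.70 ± 0.68 (SD, n = 7), had camera adjusted p = 0.820 and adjusted p = 0.778 with an estimated correlation. With protein-coding scaling these means were 0.39 (exact p = 0.0625) and 0.35 (exact p = 0.0469). HSPA1B and HLA-B were higher in 6 of 7 pairs.

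None of the fibroblast, endothelial, macrophage, erythroid and hepatocyte lists had the same direction in 7 of 7 pairs. Fibroblast and matrix genes differed by 0.11 ± 1.12 (SD, n = 7), from -1.05 in CRC patient 2 to 2.43 in CRC patient 4, and by -0.15 with protein-coding scaling. Endothelial genes differed by 0.49 ± 1.08 (SD, n = 7), from -0.46 in melanoma patient 2 to 2.51 in CRC patient 4, or 0.26 with protein-coding scaling. Macrophage genes differed by 0.31 ± 1.12 (SD, n = 7), from -1.87 in melanoma patient 2 to 1.32 in melanoma patient 1, by 0.02 with protein-coding scaling and by -0.06 after quantile normalization. Erythroid genes differed by -0.63 ± 0.77 (SD, n = 7), or -0.91 with protein-coding scaling, lower in 5 of 7 pairs, with an exact p of 0.0938 and a camera adjusted p = 0.0967 with an estimated correlation. Hepatocyte genes differed by -5.94 in CRC patient 2 and by 0.11 to 1.27 in the other 6 pairs, so their mean of -0.43 rests on 1 patient. No member of these 5 lists passed adjusted over the list alone.

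**Figure D3:**
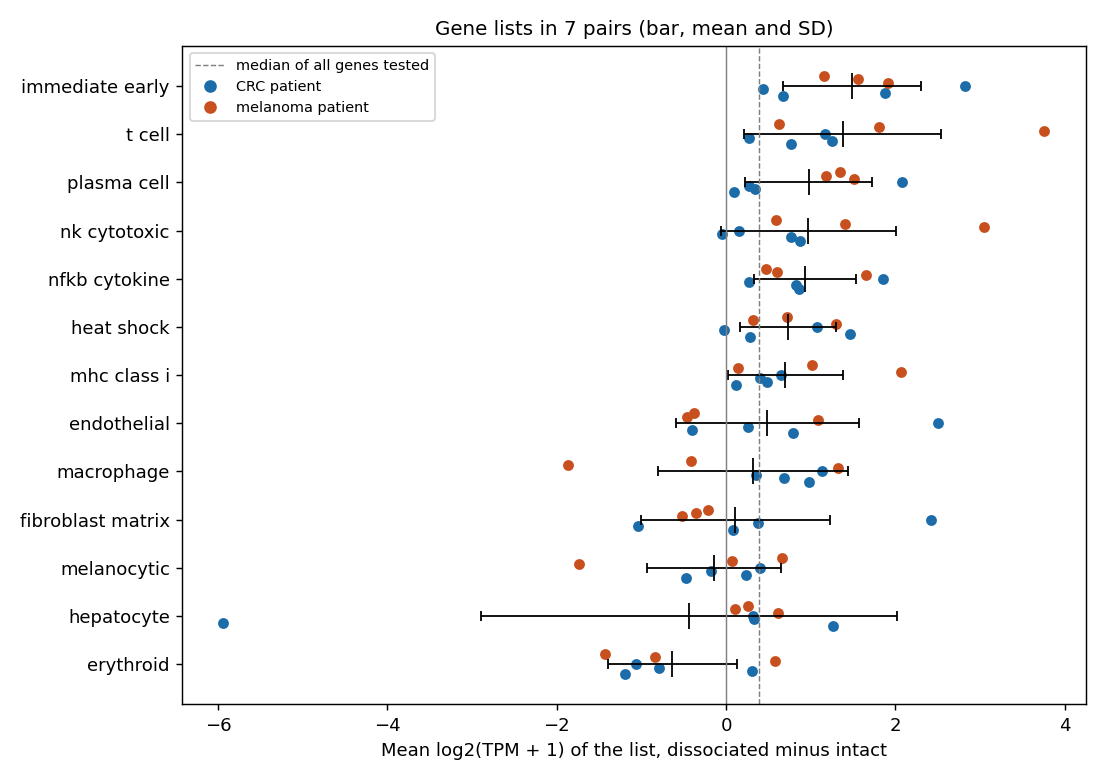
Mean log2(TPM + 1) of 13 gene lists, dissociated minus intact; each point is 1 patient, bars give the mean and SD of 7 pairs, and the dashed line is the median of all genes tested. Immediate-early and T cell points lie above 0 in 7 of 7 pairs, and the hepatocyte point at -5.94 stands apart.

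B cell genes differed by 0.59 ± 0.58 (SD, n = 7), dendritic cell genes by 0.64 ± 0.77, mast cell genes by 0.42 ± 0.68 and neutrophil genes by 0.27 ± 0.79. The largest mast cell difference was 1.80 in CRC patient 1, and the largest neutrophil difference was 1.69 in melanoma patient 1. Class II MHC genes differed by 0.58 ± 1.01, interferon response genes by 0.44 ± 0.53, hypoxia genes by 0.50 ± 0.33 and integrated stress response genes by 0.34 ± 0.20. Metallothionein genes differed by 0.46 ± 0.76, cell cycle genes by 0.23 ± 0.42, mitochondrially encoded genes by 0.69 ± 1.18, nuclear genes of oxidative phosphorylation by 0.24 ± 0.34 and ribosomal protein genes by 0.30 ± 0.32. Basement membrane genes differed by 0.28 ± 0.87, smooth muscle and pericyte genes by 0.14 ± 0.56, adipocyte genes by 0.03 ± 0.47, with a median over genes of -0.03, and glial genes by 0.44 ± 0.71. CRC patient 4 had the largest basement membrane and smooth muscle differences, 2.04 and 0.89. Intestinal epithelial genes differed by 0.21 ± 0.26, melanocytic genes by -0.15 ± 0.79, adrenocortical genes by -0.27 ± 0.78 and keratinocyte genes by 0.21 ± 0.42. With protein-coding scaling the sign turned for cell cycle (-0.08), oxidative phosphorylation (-0.12), ribosomal protein (-0.07), basement membrane (-0.03), smooth muscle (-0.10) and adipocyte genes (-0.12). After quantile normalization it turned also for integrated stress response (-0.09), intestinal (-0.05), neutrophil (-0.08) and keratinocyte genes (-0.05), while ribosomal protein genes stood at 0.12. Among these lists, IRF1, CD79A, DNAJB9 and LIPE were the members that rose adjusted over the list alone. None of them did with protein-coding scaling. In all, 8 of the 33 lists were higher in 7 of 7 pairs with an exact p of 0.0156, among them also the MHC class I, hypoxia, integrated stress response and dendritic cell lists. With protein-coding scaling hypoxia genes were higher in 5 of 7 pairs (0.20, exact p = 0.172), integrated stress response genes in 3 of 7 (0.04, exact p = 0.781), and MHC class I and plasma cell genes in 6 of 7. As deposited, the integrated stress value lay below the median shift of all genes. None of the 33 lists passed the exact test after adjustment. With 0.0156 as the smallest exact p of 7 pairs, a single list cannot pass that adjustment alone, and the 8 lists at that p stood at an adjusted p of 0.0645.

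Over all genes, no single gene passed the preparation comparison. limma called 0 of 16080 genes, with a smallest adjusted p of 0.0703, while 3883 had an unadjusted p under 0.05, 3798 higher and 85 lower. With protein-coding scaling, 1236 were higher and 250 lower at that level, and after quantile normalization 764 were higher and 525 lower. The higher genes with the smallest p were NR4A2, ZFP36 and GOLGA8N, a golgin family gene on chromosome 15 with many near copies, at 1.68 on the log2 scale. The lower ones were small RNAs: SNORA38 on chromosome 6 at -1.92, SNORA71D on chromosome 20 at -1.32 and RNA5S1, a 5S ribosomal RNA gene on chromosome 1 with identical copies, at -3.41, whose mean TPM was 5961 in intact tissue and 963 in dissociated cells. None of these 6 passed the threshold. The count depended on single patients. Without CRC patient 3 limma called 6 genes, and without CRC patient 1 it called 349 of 15592 genes, 331 higher and 18 lower, and 0 with either protein-coding scaling or quantile normalization. The 349 included 16 immediate-early genes, 4 plasma cell genes, 4 cytokine and NF-kB genes, 2 heat shock genes and 1 T cell gene.

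In CRC, limma called 0 genes (smallest adjusted p = 0.0768), and 2565 had an unadjusted p under 0.05. The smallest p belonged to PLA2G12A at 3.34, JUND at 2.54 and AC091564.7 at 2.63, and to ABCF2 at -2.48, SLC3A1 at -1.70 and SCARNA16 at -3.15, none past the threshold. In melanoma 1 gene passed, the microRNA gene MIR597 on chromosome 8 (9741672 to 9741768), with an adjusted p of 0.0426. It was listed at 0 in all intact libraries and in the dissociated CRC libraries, and at a mean TPM of 16.8 ± 10.1 (SD, n = 3) in dissociated melanoma. The CRC pairs, all at 0, thus add no residual to the spread that both tumour types share in this fit, which makes its p smaller. MIR597 did not pass with protein-coding scaling, nor without any one of CRC patients 2, 3 and 4 or melanoma patients 1, 2 and 3, where limma called 0 genes. With melanoma fitted alone limma called 1139 genes, and 0 with protein-coding scaling. RNU5B-1, SNORA52 and SNORA24 had the smallest p among lower genes. RNU5B-1 was listed at 0 in dissociated melanoma and at a mean TPM of 9.49 in intact melanoma, and SNORA52 and SNORA24 differed by -1.96 and -2.12. The difference of the preparation effects between tumour types gave 0 genes (smallest adjusted p = 0.454), and 628 genes had an unadjusted p under 0.05. Its smallest p belonged to MIR597, AC104451.1 and AC020550.1 among higher genes and to MIR1244-1, SNORD60 and AC091564.7 among lower genes. On simulated data this comparison recovered 2.99% of genes changed by 2 on the log2 scale and 42.4% of those changed by 4. For the lists, the 35 splits of the patients give no exact permutation p under 0.0286, which a single list cannot carry past the adjustment over 33 lists, so a difference between tumour types was neither shown nor excluded.

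Melanoma and CRC differed in lineage genes in intact tissue. limma called 28 of 13361 genes, all higher in melanoma, and 8 of 16 tested melanocytic genes were among them, or 13 adjusted over the list alone. PMEL, a structural protein of pigment granules on chromosome 12, had a log2 fold change of 9.23 ± 1.01 (SE) and an adjusted p of 0.0110. MLANA, a melanocyte antigen on chromosome 9, reached a mean TPM of 500 ± 318 (SD, n = 3) in melanoma and 0.177 ± 0.220 (SD, n = 4) in CRC. S100B, MIA, EDNRB (an endothelin receptor), GPM6B and BIRC7 were higher by 5.54 to 6.80. SLC24A5, an exchanger of pigment cells, was listed at 0 in all intact CRC libraries and at a mean TPM of 91.4 in intact melanoma. SNORD116-21 was listed at 0 in intact CRC and at a mean TPM of 208 in intact melanoma, but at 112 in dissociated CRC and 4.43 in dissociated melanoma. No gene passed as lower in melanoma. Among the lower genes, KRT18, a keratin of simple epithelia, had a difference of -5.86 ± 1.02 (SE) with an adjusted p of 0.0770, SNORA71E of -3.76 and ABCF2 of -2.70. Of 17 intestinal epithelial genes, 10 were lower adjusted over the list alone, with KRT18, LGALS4 and VIL1 first. Of 7 metallothionein genes 2, MT1X and MT1M, were lower in melanoma adjusted over the list alone. The melanocytic list had a camera adjusted p = 0.0820 with an estimated correlation, the intestinal list adjusted p = 0.516, and the metallothionein list adjusted p = 0.558. Without the filter on low values, 4 of the 28 genes passed and no others. Leaving out patients moved the count from 0 to 46, so it depends on single patients. It was 0 without melanoma patient 2 or 3, 1 without melanoma patient 1, 3 without CRC patient 2, 10 without CRC patient 4 and 46 without CRC patient 1.

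In dissociated cells, limma called 0 of 14456 genes between melanoma and CRC (smallest adjusted p = 0.0604), and 1772 had an unadjusted p under 0.05. Of the melanocytic genes, 13 of 13 tested members were higher in melanoma adjusted over the list alone. MIA had a difference of 5.77 ± 0.61 (SE), TUBB4A, a neuronal tubulin, of 5.05, and AC020550.1 was listed at 0 in dissociated CRC and at a mean TPM of 14.4 in dissociated melanoma. SNORD60, GABRE and AC008738.5 had the smallest p among lower genes, at -2.98, -4.56 and -3.18. None of these 6 passed the threshold over all genes. Of 21 intestinal epithelial genes 10 were lower adjusted over the list alone, led by CEACAM5 at -6.70 and LGALS4 at -5.01, as were ALB and FGB of the hepatocyte list. With an estimated correlation, camera gave adjusted p = 0.362 for the melanocytic, intestinal and hepatocyte lists. Without melanoma patient 1, 15 genes passed.

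Paired libraries resembled each other across genes. The correlation of log2(TPM + 1) between an intact library and its own dissociated library averaged 0.882 ± 0.080 (SD, n = 7). It averaged 0.731 with dissociated libraries of other patients of the same tumour type. By an exact permutation of patients within tumour type, one-sided over all assignments, p was 0.00694, the smallest that the design can give. All 7 intact libraries correlated best with the dissociated library of their own patient, and 6 of 7 dissociated libraries with their own intact library. The dissociated library of CRC patient 1 correlated better with the intact libraries of melanoma patient 1 (0.842), CRC patient 3 (0.784), melanoma patient 2 (0.750) and CRC patient 2 (0.716) than with its own. CRC patient 1 had the lowest own-pair value, 0.715, and the others lay between 0.875 and 0.952. The intact library of CRC patient 1 correlated at only 0.515 to 0.604 with the dissociated libraries of other patients. It also had the fewest genes with a TPM of at least 0.1 of all libraries, 14455.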

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

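Tests chosen only after the result was seen are the scaling and T cell tests of immediate-early genes, both tests of T cell genes, the short RNA test, the split count with protein-coding scaling, and the list counts, scalings and swaps without CRC patient 1. Leaving out each patient, the nuclear RNA test and the other counts over splits were set before their results were seen. Of 88 groups of values tested for a sample far from the others, 7 were found, and chance gives about 1 in 20.

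The own-pair correlation of CRC patient 1 was 0.715, far below the other 6. Other differences in 2 CRC patients stood apart among 7 pairs: hepatocyte genes at -5.94 and keratinocyte genes at 1.05 in CRC patient 2, and fibroblast and matrix genes at 2.43 in CRC patient 4. Glial genes at 1.99 in CRC patient 4 and dendritic cell genes at 2.24 in melanoma patient 1 also stood apart. Among the 4 intact CRC libraries, GPM6B stood at a log2(TPM + 1) of 2.05 in patient 4, against at most 0.21 in the others.

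Immediate-early genes were higher in dissociated cells in 7 of 7 pairs. The scaling of TPM as the whole cause is argued against, since the list's mean difference stayed at 1.19 with protein-coding genes set to one total, positive in 7 of 7 pairs. A larger share of T cells, which express these genes, stays open. Over the 7 pairs the list's difference followed that of the T cell list at a Spearman rho of 0.714 (exact permutation p = 0.0881) and a Pearson r of 0.462 (exact permutation p = 0.306). The immediate-early list rose more than the T cell list in 4 of 7 pairs. Without the 2 pairs farthest from the median of the T cell list, Pearson r was 0.405, so the pairs are too few to decide. A response of the cells to dissociation is a biological explanation, but the design cannot part it from other differences between the 2 samples of a patient. It stays an untested hypothesis.

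T cell genes were higher in dissociated cells in 7 of 7 pairs. Scaling as the whole cause is argued against by a mean difference of 1.17 with protein-coding genes set to one total. After quantile normalization 3 of 20 members passed, but the list still differed by 1.02, higher in 7 of 7 pairs. A lower share of stromal and tumour cells, which raises every other cell type alike, stays open, since the lists set against it were picked after their values were seen. The cytotoxic, plasma cell, dendritic cell and B cell lists, which rose by 0.97, 0.98, 0.64 and 0.59, were not among them. The neutrophil list lay at -1.11 ± 0.97 (SD, n = 7) relative to the T cell list, below it in 7 of 7 pairs (exact sign-flip p = 0.0156, adjusted p = 0.0469 over 3 lists picked with their bound after the values were seen), from a mean log2(TPM + 1) in intact tissue of 1.67 against 1.53. The macrophage list at -1.06, below it in 5 of 7 pairs (exact p = 0.109), and the mast cell list at -0.96 (exact p = 0.156) do not decide by themselves, and a loss of neutrophils beside such a shift stays open, as does a change in the T cells, which were not tested. The stromal and tumour lists, read after their values were seen, do not show a fall in every pair. With protein-coding scaling, fibroblast and matrix genes were higher in 3 of 7 pairs and endothelial genes in 4. CRC patient 1 had 0.07 for fibroblast, 0.20 for intestinal and 0.74 for T cell genes. Melanoma patient 1 had -1.16 for fibroblast, -2.24 for melanocytic and 3.15 for T cell genes.

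The snoRNA share of TPM was lower in dissociated cells in 7 of 7 pairs. In CRC patient 1 it differed by -7.73 percentage points, while SNORD3A alone differed by -16.5. The other snoRNA genes together thus held a larger share in dissociated cells of that patient. A loss of short RNAs of any class was checked only in small nuclear, small Cajal body and ribosomal RNA genes under 300 bases. Other short classes, such as microRNA genes, were left out, so a loss of every class was not tested. Of the genes checked, 27 of 30 lay below protein-coding genes, with a median log2 difference of -1.25, which goes with a loss in those classes. The 196 snoRNA genes had a median of -0.66. Many of these short RNAs are nuclear too, so a lower yield of nuclear RNA cannot be told apart. The long nuclear RNAs asked for were MALAT1, NEAT1, KCNQ1OT1, MEG3 and TUG1, and no others. Only 2 of them were among the genes tested, MALAT1 at 0.65 and MEG3 at -0.83 relative to protein-coding genes, with a median of -0.0889. No biological explanation was tested.

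Other splits of the samples were counted for each gene-wide result. For the all-patients preparation comparison, the real count was 0, which all 64 within-pair swaps reach whatever the data (highest other 0), so it says nothing about chance. At an unadjusted p under 0.05 the real pairing gave 3883 genes, and 1 of 64 swaps reached it (highest other 2655). That share is under 0.05, but it is the smallest that 64 swaps can give, and the count includes the upward shift of TPM. With protein-coding scaling, chosen after seeing the data, the gap was smaller, 1486 genes against 1296. Without CRC patient 1, 1 of 32 swaps reached 349 genes (highest other 0), but that fit was chosen after the counts of all left-out patients were seen and gave 0 genes with protein-coding scaling or quantile normalization, so chance is not excluded for it. For CRC the real count was 0 as well, reached by 32 of 32 splits of the libraries. One of those splits gave 41 genes, which points to a structure of those samples whose origin was not tested; these splits need not part the 2 libraries of a patient, and among the 8 swaps within pairs the highest other count was 0. For melanoma, 10 splits of the same kind and 4 swaps within pairs are too few for a share under 0.05; the real count was 1 and the highest other 0 in both. For the difference between tumour types, the real count was 0 (highest other 1), as it was for tumour type in dissociated cells (highest other 18); all 35 splits reach 0 by construction, so neither says anything about chance. For tumour type in intact tissue, 1 of 35 splits reached 28 genes (highest other 2). That share is under 0.05, although it is the smallest that 35 splits can give and the count depends on single patients.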

How the results depend on the processing

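The fit without CRC patient 1 by scaling, the protein-coding scaling and the robust prior were chosen after seeing the data. Depth is not known from TPM, so its limit cannot be given. The cause of a moved value was not tested unless stated.

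The counts for all patients, CRC, the tumour type difference and tumour type in dissociated cells were 0 under every setting that kept all patients. For melanoma, the 1 gene became 0 with a pseudocount of 0.1, without a trend and with protein-coding scaling, 2 without the patient block, and 1139 (1035 higher, 104 lower) with melanoma fitted alone; there the prior degrees of freedom rose from 4.43 to 13.4, other swaps gave at most 3 genes, and protein-coding scaling gave 0. With no filter and with quantile normalization the count stayed at 1 but for another gene, lower in dissociated cells. It was 0 with the authors' scores, which remove the preparation difference by construction. The 28 genes of tumour type in intact tissue became 4 without a filter, all of them among the 28. Without the patient block, the other calls over all genes did not change.

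Leaving out each patient gave 0 to 349 genes for all patients (349 without CRC patient 1, 6 without CRC patient 3), 0 for CRC, 0 to 2 for melanoma, 0 for the difference, 0 to 46 for intact tissue and 0 to 15 for dissociated cells. The list differences ranged from 1.27 to 1.67 for immediate-early, 1.01 to 1.56 for T cell, 0.78 to 1.04 for cytokine and 0.79 to 1.23 for plasma cell genes, and the own-pair correlation from 0.868 to 0.907. Members adjusted over the list alone ranged from 26 to 28, 7 to 19, 4 to 13 and 4 to 6 in that order. Library differences ranged from 929.3 to 1208 genes, -9.87 to -6.47 percentage points for the 100 highest genes, -15.7 to -11.9 for snoRNA and 8.24 to 12.2 for protein-coding genes.

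With the authors' scores the list differences were 0.0145 for immediate-early, 0.0106 for T cell, 0.0105 for cytokine and -0.00286 for plasma cell genes, again by construction. After quantile normalization plasma cell genes differed by 0.63 (exact p = 0.0781) and integrated stress response genes by -0.0874. T cell members passing were 7 without a filter, 3 after quantile normalization and 0 without the patient block. Cytokine members were 3 after quantile normalization, 3 with protein-coding scaling and 0 without the block. Plasma cell members were 3 after quantile normalization, 1 without immunoglobulin and the other left-out genes, and 0 without the block. Genes with a TPM of at least 0.1 differed by 883.6, which did not pass (exact p = 0.234). Over all 33 lists with all patients kept, 19 of 162 list differences under an alternative other than the authors' scores turned sign: 11 after quantile normalization, 7 with protein-coding scaling and 1 with a pseudocount of 0.1; 1 of them had an exact p under 0.05 before, and 9 others lost that. The own-pair correlation kept its side in 4 of 4 alternatives.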

Other observations

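The scaling and fit checks here were chosen after the result was seen. Without CRC patient 1, the 18 genes that were lower in dissociated cells were small RNAs or related genes: 14 snoRNA genes, 2 small Cajal body RNA genes, 1 ribosomal RNA gene and 1 ribosomal RNA pseudogene. The 331 higher genes included 272 protein-coding genes and 16 transcribed and 9 other unprocessed pseudogenes, and also 2 snoRNA genes, SNORD82 at 2.19 and SNORD99 at 2.07 on the log2 scale. Several named among them belong to families whose copies share reads, such as STAG3L5P at 2.32, PMS2P3 at 1.25 and NPIPB3 at 1.58 on the log2 scale; these 3 were chosen after their values were seen. The circadian regulator PER1 rose by 1.90 ± 0.22 (SE) and CCNL1, a cyclin linked to splicing, by 1.51 ± 0.21 (SE) in the same fit, also chosen after their values were seen.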
